A study of Mus musculus with 2 samples.

How the data were processed

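DNase-seq data of 2 libraries of spleen tissue from male B6CASTF1/J mice aged 4 days were used, labelled as biological replicates 1 and 2 of 1 group. For each library the authors deposited 2 peak lists, a list of footprints and a list of positions with a false discovery rate, all on mm10 per the file headers and the listing that came with them. The peaks carry a signal per peak as deposited, called on each library alone. Its scale is not stated. Signals below 1 were whole multiples of 0.00538 in replicate 1 and 0.00409 in replicate 2, within 0.02 of a step, so each library was scaled by a factor of its own, and the factor was 1.32 times as large in replicate 1. Footprints carry a deposited FDR (q-value) that is 0.01 in every line, so they could not be ranked. The position lists carry the authors' FDR (q-value) per stretch of bases and hold only values under 0.05. Every peak of the less strict list touched such a position, and every peak of the stricter list touched one with an FDR of at most 0.001. The aligner, the peak and footprint callers and their versions are not given in the sources used here, nor is how reads carrying CAST/EiJ alleles were placed on the C57BL/6J reference. No read totals were used, so depth is unknown, no counting interval could be given, and weak peaks of one library missing from the other may lie under its limit of detection.

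The less strict lists held 80323 and 88723 peaks with a median width of 180 bp and median signals of 0.796 and 0.650. The stricter lists held 51123 and 56521. Because the deposited lists give no summit, midpoints were used to measure the distance of regions to start sites. Overlapping peaks of both libraries (at least 1 bp) were merged into regions, and a region with peaks of both was called shared, with the highest peak signal per library as its signal. Annotation used 21827 protein-coding genes with 41403 start sites on GRCm38. A promoter was open where a shared region overlapped the 1 kb on either side of a start site, and in the runs on 1 library where a peak of that library did. A shared region can reach the window when the peak of 1 library does not, and 2 peaks in the window need not overlap, so the 2 counts differ for some genes. Promoter signal is the highest peak within 1 kb of any start site of the gene. CpG-poor means an observed over expected CpG ratio under 0.5 in the 1 kb window on the most upstream start site, which held for 9795 genes. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, bedtools 2.31.1 and samtools 1.23.1.

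The 21 gene lists, the 38 motif consensuses, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The lists cover erythroid, megakaryocyte, B, T, natural killer, neutrophil, macrophage, dendritic, mast, stem, endothelial, stroma, cell cycle, housekeeping, hepatocyte, pancreas, neuron, muscle, adipocyte, gut and olfactory receptor genes. They share members, such as Kit and Gata2 in the mast and stem cell lists and Flt3 in the stem and dendritic cell lists. One erythroid gene of the list, Ahsp, was absent from the annotation used here. Named were the 2 members of each list with the strongest promoter, up to 2 without a promoter peak and up to 2 with a peak in 1 library (first in alphabetical order), a fixed set of loci, the 10 genes with the most peaks within 50 kb by the lower of the 2 libraries, the 5 strongest distal regions, the 5 largest ratios in each direction among regions above the median signal, and the 5 largest and 5 smallest odds ratios among motifs with at least 50 matches. Other genes named are said to be chosen after their values were seen, and a few genes that the rule names are not reported here.

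Open promoters of a list were compared with those of all other protein-coding genes by two-sided Fisher's exact test, and 0.5 was added to each cell for odds ratios and their 95% intervals. Regions within 50 kb of start sites were counted per gene, and list medians were compared with 10000 random lists of equal size matched on the number of neighbouring start sites. The log2 ratio of the 2 signals at shared regions near listed genes was centred on its median over all shared regions. It was compared with 10000 random lists of as many genes, which were not matched on the number of regions. Permutation p-values are two-sided, and Benjamini-Hochberg adjustment was made over the lists. Overlap was compared with 100 shuffles of peaks within chromosomes, and annotation and footprint shares with 20 shuffles. Motifs were counted in footprints found in both libraries with 5 bp added on each side (median 28 bp) and in windows of equal width in the same regions that touch no footprint. Such a window was found for 76.1% of footprints in shared regions, and the rest were left out. Binding itself was not measured, so a match names a sequence and not the protein bound.

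Alternatives were each library alone, the stricter peak list, reciprocal overlap of 50%, the stronger peaks or equal numbers of peaks, promoters within 500 or 2500 bp, CpG-poor promoters alone, windows of 20 and 100 kb, distal regions alone, quantile normalization, comparison within quintiles of signal, footprints without flanks, the reversed consensus, and regions per gene on X. Means in place of medians for region counts, and centring of the ratio within bins of signal, GC content and promoter class, were added after seeing the data.

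The tests were tested on simulated data built on the 21827 genes. With the odds of an open promoter raised 8 times, the list test called 93.3% of lists of 46 genes, 68.3% of lists of 25 and 20.0% of lists of 12, and it called at most 1.11% of unchanged lists. With 5 regions added per gene, the test of region counts called all lists of 46 and 25 genes and 40.0% of lists of 12, and it called 1 of 15 unchanged lists of 12. With a log2 ratio raised by 0.15, the ratio test called all lists of 46 genes, 60.0% of lists of 25 and 80.0% of lists of 12, from 5 lists per size. The motif test found 8 of 8 planted motifs and called 1 of 30 that were not planted. Simulated lists were random draws from all genes, so they did not differ in CpG content as the real lists do. Simulated footprint and control sequences had equal base composition, unlike the real windows. Simulated region counts and log2 ratios were drawn independently, whereas neighbouring genes of a real list share regions. The shares of false calls therefore do not cover calls that arise from CpG content, base composition or listed genes lying together. In the promoter and region count tests, a list of about 12 genes that did not pass is weakly informative. Changes of the odds smaller than 8 times were not simulated. How often the promoter test would call them is therefore unknown for lists of any size.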

Results

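Chromatin accessibility was measured by DNase-seq, in which the nuclease DNase I preferentially cuts open chromatin, in spleen tissue of male mice 4 days after birth. The mice were B6CASTF1/J, first-generation hybrids of a C57BL/6J and a CAST/EiJ parent. The labels name 1 group of 2 biological replicates, so there was no contrast between conditions. The comparisons are therefore between the replicates, between gene lists, between classes of region and between chromosomes. At this age the mouse spleen is still a site of blood formation, and the gene lists cover the cell types that such a spleen could hold, together with tissues it should lack. Replicate 1 had 80323 peaks and 217159 footprints, and replicate 2 had 88723 peaks and 252901 footprints. A footprint is a short stretch inside open chromatin that is protected from the enzyme. The number of reads behind each value is unknown. Positions refer to mm10, the mouse assembly GRCm38. Signal is the authors' value per peak, whose scale is not stated, and errors are the SD of the 2 libraries.

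Promoters of red blood cell genes were open in nearly the whole list. Overlapping peaks of both libraries were merged into shared regions, and a promoter was counted as open where a shared region reached within 1 kb of an annotated transcription start site. This held for 13025 of 21827 protein-coding genes (59.7%). A peak of each library taken separately, overlapping or not, lay within 1 kb for 13121 genes, and statements on peaks in 1 or both libraries follow this second count. Of 46 erythroid genes, 43 were open (93.5%). The strongest were Epb41, which encodes a protein of the red cell membrane skeleton (chromosome 4, 131923413 to 132075321, signal 28.7 ± 1.03, n = 2), and Slc25a38, a mitochondrial carrier needed for haem synthesis (chromosome 9, 120110374 to 120124504, signal 18.5 ± 3.67, n = 2). Among the erythroid transcription factors, the signal was 2.68 ± 0.464 at Gata1 (chromosome X, 7959260 to 7978071), 3.90 ± 0.624 at Klf1 (chromosome 8, 84901928 to 84905291) and 6.31 ± 2.08 at Tal1 (chromosome 4, 115056426 to 115071755). The adult beta globin gene Hbb-bt (chromosome 7, 103812524 to 103813996) had a promoter signal of 4.29 ± 0.320, a value that is uncertain because its neighbour Hbb-bs is a near-identical copy. The embryonic globin genes Hbb-bh1 and Hbb-y had no promoter peak in either library. The alpha globin genes Hba-a1 (chromosome 11, 32283511 to 32284465) and Hba-a2 (chromosome 11, 32296489 to 32297298) had none either, although 18 and 17 regions shared by both libraries lay within 50 kb of their start sites. In the reference, 75.0% and 81.0% of the 31-base words within 1 kb of these start sites occur more than once. The remaining erythroid gene without an open promoter was Slc25a37, the mitochondrial iron carrier, named after its values were seen, where all 31-base words around the start site are repeated. The erythroid share exceeded the 59.6% of the other genes (odds ratio 8.42, 95% interval 2.83 to 25.0, adjusted p = 2.95e-06, two-sided Fisher's exact test, Benjamini-Hochberg over 21 lists), with 43 open promoters in each library alone. Genes were the units of this test and are not independent replicates.

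Genes of dividing cells and stem cells were also open more often than other genes. All 24 cell cycle genes had open promoters (adjusted p = 3.44e-05, Fisher's exact test), with Ccna2, the S-phase and mitotic cyclin A2, at 19.2 ± 0.546 and Birc5, the mitotic regulator survivin, at 18.1 ± 2.61 (n = 2). All 20 housekeeping genes were open as well (adjusted p = 1.61e-04, Fisher's exact test), led by Eef2, a translation elongation factor, at 24.2 ± 2.81 and Actb, cytoplasmic beta actin, at 24.2 ± 2.12. Of 21 stem and progenitor genes, 19 were open (odds ratio 5.28, adjusted p = 0.00926, Fisher's exact test), with the highest signal at Lyl1 (12.6 ± 2.25) and Mllt3 (12.3 ± 2.20), both regulators of blood stem cells. Hoxa9 had a promoter peak in replicate 1 only, and Prdm16 in replicate 2 only. The stem cell call was lost with the stricter peak list (adjusted p = 0.145, Fisher's exact test), with the stronger peaks (0.218) and within 500 bp of a start site (0.30), the range over 7 alternatives being 0.00323 to 0.30. The cell cycle and housekeeping lists are rich in CpG (median observed over expected 0.778 and 0.775), and 89.2% of all CpG-rich promoters were open. They were not tested against CpG-rich promoters alone.

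Each lymphoid and myeloid list was tested against all other genes. Of 26 B cell genes, 20 were open (76.9%, odds ratio 2.13, adjusted p = 0.151, Fisher's exact test). The B lineage transcription factors Bach2 (4.42 ± 0.654), Ebf1 (3.51 ± 0.724) and Pax5 (1.20 ± 0.239) and the antigen receptor component Cd79a (1.79 ± 0.365) had promoter peaks in both libraries (n = 2). The Fc receptor genes Fcer2a and Fcmr had none. Of 24 T cell genes, 11 were open (adjusted p = 0.261, Fisher's exact test), a lower share that passed with the stricter peak list (5 of 24, 0.00277) and with the stronger peaks (0.00568). Among the open ones were the kinase gene Lck (1.34 ± 0.466) and the surface antigen gene Cd5 (1.18 ± 0.232). The T cell receptor complex genes Cd3e and Cd247 and the costimulatory gene Cd27 had no promoter peak. Cd8a had a weak one in replicate 2 only and Gata3 in replicate 1 only. Natural killer and cytotoxic genes were open less often than other genes, in 4 of 15 cases (odds ratio 0.264, adjusted p = 0.0259, Fisher's exact test). This call was lost among CpG-poor promoters, which 13 of the 15 genes have (odds ratio 1.09, adjusted p = 1, Fisher's exact test). Itga2 was the strongest (0.936 ± 0.122), followed by Cd244a (0.556 ± 0.0407), and the granzyme genes Gzma and Gzmb had no peak. Neutrophil granule genes were open in 13 of 23 cases (adjusted p = 0.833, Fisher's exact test), with S100a8 at 1.97 ± 0.237 and Gfi1 at 1.56 and 1.59 in peaks of replicates 1 and 2 that do not overlap, and no peak at the elastase gene Elane or the formyl peptide receptor gene Fpr1. Ctsg had a peak in replicate 1 only and Itgam in replicate 2 only.

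Monocyte and macrophage genes were open in 8 of 26 cases, a lower share than among other genes (odds ratio 0.310, adjusted p = 0.0109, Fisher's exact test). The iron exporter gene Slc40a1 (5.77 ± 1.83) and the haem oxygenase gene Hmox1 (3.73 ± 0.751) were the strongest. The complement genes C1qa and C1qb and Spic, a transcription factor of iron-recycling splenic macrophages, had no promoter peak. Csf1r, the receptor for macrophage colony-stimulating factor, and Axl had one in replicate 2 only. This call was lost in replicate 2 alone (adjusted p = 0.0782 by Fisher's exact test, range over 7 alternatives 0.00277 to 0.951). Dendritic cell and antigen presentation genes did not pass (10 of 15 open, adjusted p = 0.833, Fisher's exact test), with Zbtb46 at 6.96 ± 0.798 and Bst2 at 6.04 ± 1.15 and no peak at Cd209a or Clec9a. Mast cell and basophil genes were open in 2 of 11 cases (odds ratio 0.178, adjusted p = 0.0185, Fisher's exact test). The 2 were the receptor gene Kit (2.85 ± 0.451) and Gata2 (1.08 ± 0.0537), which the stem cell list also holds, and the protease genes Cma1 and Cpa3 had no peak. Megakaryocyte and platelet genes did not pass (9 of 22 open, adjusted p = 0.125, Fisher's exact test), but passed as lower with the stricter peak list (6 of 22, 0.0214) and the stronger peaks (0.0131), with Nbeal2 at 7.60 ± 1.47, Itgb3 at 2.14 ± 0.504 and no peak at Pf4, Clec1b or Gp6. Gp1ba had a peak in replicate 2 only and Gp1bb in replicate 1 only.

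Lists of supporting cells did not pass in the main comparison. Spleen stroma genes were open in 12 of 25 cases (adjusted p = 0.359, Fisher's exact test) and endothelial genes in 10 of 23 (adjusted p = 0.180, Fisher's exact test). Both passed as lower by Fisher's exact test with the stricter peak list (7 of 25, adjusted p = 0.0137, and 5 of 23, 0.00431) and with the stronger peaks (0.0217 and 0.00269), and stroma also within 500 bp (0.0430). In the libraries alone, stroma had 15 and 16 open promoters and endothelial genes 14 and 11. In the stroma list, Madcam1, an adhesion molecule of vessels of the spleen's marginal sinus, had a promoter signal of 2.57 ± 0.384. The spleen homeobox gene Tlx1 had a weak peak in each library (0.349 and 0.470), at places that do not overlap, and Nkx2-5, Ccl19 and Col3a1 had none. Nr2f1 had a peak in replicate 2 only and Pdgfrb in replicate 1 only. In the endothelial list, Egfl7 (1.5 ± 0.121) and Eng (1.19 ± 0.236) were the strongest, Cdh5 and Emcn had no promoter peak, and Cldn5 and Ramp2 had one in replicate 1 only. All values are over both libraries (n = 2).

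Marker genes of other organs were mostly closed. Hepatocyte genes were open in 1 of 22 cases (odds ratio 0.0470, adjusted p = 7.31e-07, Fisher's exact test), the 1 being Apob, and Alb and Ahsg had no peak. Within 500 and 2500 bp of a start site, 0 and 4 of the 22 were open (odds ratios 0.0159 and 0.146). Pancreas genes were open in 5 of 20 cases (odds ratio 0.239, adjusted p = 0.00785, Fisher's exact test), with peaks at Rbpjl and Nkx6-1 and none at Cel or Cela2a. Skeletal muscle genes were open in 6 of 18 cases (odds ratio 0.351, adjusted p = 0.0474, Fisher's exact test), and 5 had a peak of each library taken separately. The open ones included Actn3 (13.0 ± 0.167) and Mylpf (7.01 ± 0.536), whereas Acta1 and Casq1 had none and Myod1, Myf5 and Cacna1s had one in replicate 2 only. Adipocyte genes were open in 2 of 12 cases (odds ratio 0.161, adjusted p = 0.0118, Fisher's exact test), namely Lipe (8.72 ± 0.108) and Pparg (0.482 ± 0.0863), with none at Adipoq or Cfd and 1 library each at Lep and Lpl. Gut epithelium genes were open in 4 of 16 cases (odds ratio 0.243, adjusted p = 0.0175, Fisher's exact test), including Elf3 and Epcam, with none at Cdx2 or Fabp2 and replicate 1 only at Cdx1 and Cldn7. Olfactory receptor genes were open in 6 of 1133 cases (odds ratio 0.00340, 95% interval 0.00157 to 0.00735), the strongest being Olfr373 and Olfr433. In replicates 1 and 2 alone, 15 and 17 of them were open (odds ratios 0.00723 and 0.00804). Neuronal genes were open in 12 of 22 cases (odds ratio 0.804, adjusted p = 0.737, Fisher's exact test). The share was above that of other genes in replicates 1 and 2 alone (15 and 16 of 22, odds ratios 1.25 and 1.51, neither passing). It passed as lower with the stronger peaks (5 of 22, adjusted p = 0.0131, Fisher's exact test). The open ones included Grin1 (2.09 ± 0.429), Dlg4 (1.45 ± 0.0723) and Syn1 (1.10 ± 0.0382), with no peak at Elavl3 or Neurod1 and replicate 2 only at Camk2a. Some calls depended on the library or the window. Muscle was lost in replicate 2 alone and within 2500 bp (adjusted p = 0.213 and 0.464 by Fisher's exact test, range over alternatives 0.00131 to 0.746). Adipocytes were lost in replicate 1 alone and within 2500 bp (0.110 and 0.221, range 0.00390 to 0.744), and gut epithelium was lost in each library alone (0.107 and 0.110, range 0.000227 to 1).

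The share of open promoters depended on CpG content, since 89.2% of CpG-rich promoters were open against 23.4% of CpG-poor ones, and the cell type lists differ in CpG content. Among CpG-poor promoters, 26 of 28 erythroid genes were open (92.9%, odds ratio 35.0), 18 of 24 B cell genes (75.0%, odds ratio 9.36), 7 of 9 stem cell genes (77.8%, odds ratio 9.82) and 12 of 22 neutrophil genes (54.5%, odds ratio 3.90). By Fisher's exact test these shares exceeded those of the other CpG-poor genes, with adjusted p = 8.07e-14 for erythroid genes (range over 7 alternatives 8.07e-14 to 1.52e-05) and 8.30e-07 for B cell genes (range 8.30e-07 to 0.889). For stem cell genes the adjusted p was 0.00418 (range 0.00323 to 0.30), and for neutrophil genes 0.00596 (range 0.00596 to 1). With the stricter peak list over all promoters, neutrophil genes were instead open less often than other genes (6 of 23, odds ratio 0.308, adjusted p = 0.0153, Fisher's exact test). T cell genes (9 of 20) and stroma genes (8 of 17) did not pass (adjusted p = 0.102 and 0.105, Fisher's exact test). Macrophage genes (4 of 22) and natural killer genes (3 of 13) were near the CpG-poor share, and olfactory receptors were the only list that passed with a lower share. The lower shares of hepatocyte (1 of 20), mast cell (0 of 9) and pancreas genes (2 of 15) did not pass here (adjusted p = 0.130, 0.243 and 0.746, Fisher's exact test). Nor did muscle (5 of 17, odds ratio 1.44), adipocyte (1 of 10, 0.515) and gut epithelium genes (2 of 10, 0.960). Megakaryocyte (5 of 18, odds ratio 1.33) and endothelial genes (6 of 16, 2.02) had no lower share among CpG-poor promoters, and neither list passed. The B cell list also passed within 2500 bp of a start site (23 of 26 open, odds ratio 4.04).

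**Figure D1:**
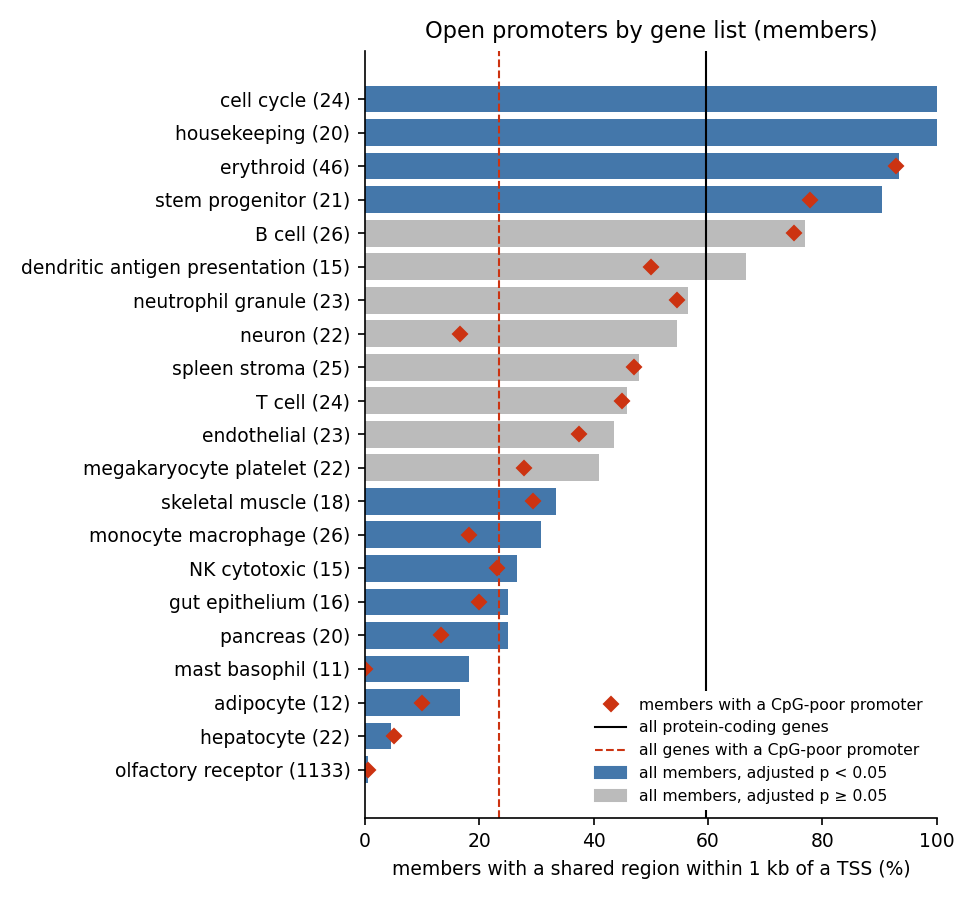
Horizontal bars give the share of each list's genes with a region shared by both libraries within 1 kb of a start site, in percent, with the number of genes in brackets, and diamonds give the same share among members with CpG-poor promoters. Vertical lines mark all protein-coding genes (59.7%) and all CpG-poor ones (23.4%); the erythroid list stands above both, at 93.5% and 92.9%.

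Open sites were also dense around erythroid genes. The median erythroid gene had 11 shared regions within 50 kb of its start site, against 5.5 in random lists with as many neighbouring start sites (95% of lists 3.5 to 7.5, adjusted permutation p = 0.0021). Housekeeping genes had 13 against 6.5 (adjusted permutation p = 0.0028), and olfactory receptor genes had 0 against 8 (adjusted permutation p = 0.0021). The raw p of 0.0002 behind the values of 0.0021 is the smallest that 10000 lists can give. No other list passed by its median. B cell genes had 7.5 against 6.5, T cell genes 5 against 4.5, neutrophil genes 7 against 6 and stem cell genes 6 against 3. By the mean, an alternative chosen after seeing the data, dendritic cell genes (11.6 against 6.27) and cell cycle genes also passed, with adjusted permutation p = 0.0042 and 0.0244. The ranges over 7 alternatives were 0.0042 to 1 and 0.0244 to 1. The dendritic cell median was 7 against 5, so a few genes with many regions may raise that list's mean. Of the 10 protein-coding genes with the most peaks in this window, 5 lie together in the major histocompatibility complex on chromosome 17. They are the peptide transporter genes Tap1 (51 shared regions) and Tap2 (55), the immunoproteasome genes Psmb8 (54) and Psmb9 (51), and H2-Ob (55). The others were Gm21887 on chromosome X (52), Prnd on chromosome 2 (37) and Gm48551 (34), Gm48552 (34) and Smim24 (33), neighbours on chromosome 10.

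The libraries shared most of their stronger peaks. Of the peaks of replicate 1, 77.3% overlapped a peak of replicate 2, and 69.7% of those of replicate 2 overlapped one of replicate 1, a mean of 73.5% ± 5.35 (n = 2). Peaks shuffled within their chromosome overlapped in 1.32% and 1.20%. The shared share rose with signal, from 23.6% in the weakest decile of the peaks of replicate 1 to 99.7% in the strongest, and from 8.06% to 99.9% in replicate 2. Merging gave 60596 regions with peaks of both libraries, 18101 with peaks of replicate 1 only and 26399 with peaks of replicate 2 only. Across the shared regions the log2 signals had a Pearson correlation of 0.978 and the signals a Spearman correlation of 0.962. The correlation is across regions, which are not independent replicates. The log2 ratio of replicate 2 to replicate 1 had a median of -0.16 and an SD of 0.33.

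**Figure D2:**
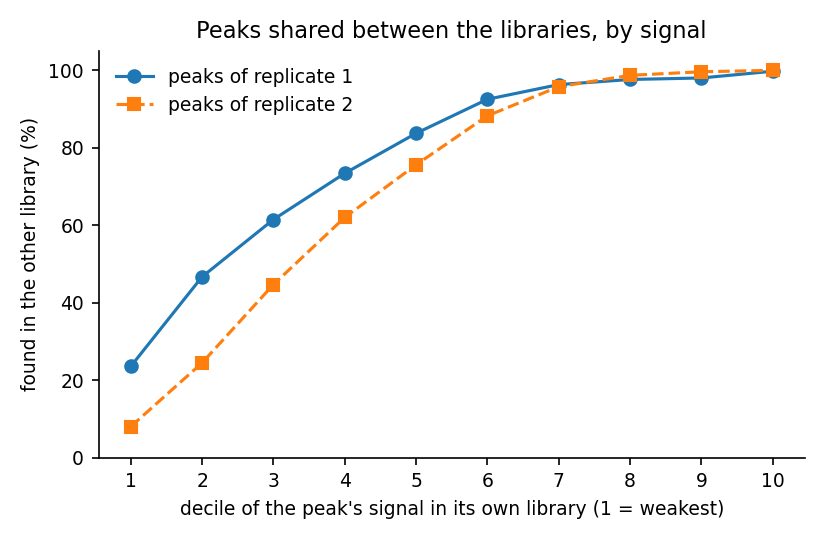
Each point is the percentage of the peaks of 1 library that overlap a peak of the other, by decile of signal within the library (1 is the weakest), with circles for replicate 1 and squares for replicate 2. The lines rise from 23.6% and 8.06% to 99.7% and 99.9%.

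Regions near erythroid genes had relatively more signal in replicate 1, and regions near B cell genes in replicate 2. After centring on all shared regions, the median log2 ratio of replicate 2 to replicate 1 was -0.11 over 504 regions within 50 kb of erythroid genes, of which 32.7% were higher in replicate 2 (adjusted permutation p = 0.0042). It was 0.14 over 210 regions near B cell genes, of which 70.5% were higher in replicate 2 (adjusted permutation p = 0.0021). Promoter signals gave the uncentred counterpart. Of 43 erythroid promoters, 39 had the higher signal in replicate 1, with medians of 6.09 and 4.46. Of 20 B cell promoters, 14 had the higher signal in replicate 2, with medians of 1.22 and 1.46. Over all genes with a promoter peak in each library, the signal was higher in replicate 1 for 10826 and in replicate 2 for 2295. The class II antigen presentation genes H2-Aa (1.5 and 3.21 in replicates 1 and 2), H2-Eb1 (1.88 and 3.68) and Cd74 (1.22 and 2.20), named after their values were seen, were higher in replicate 2. In the whole dendritic cell and antigen presentation list, 5 promoters were higher in replicate 1, among them Zbtb46 (7.52 and 6.39) and Bst2 (6.85 and 5.23), and 5 in replicate 2. Regions near the dendritic cell and antigen presentation list had a median of 0.13 (138 regions, adjusted permutation p = 0.0168). Regions near natural killer genes had one of 0.12 (65 regions, adjusted permutation p = 0.0428). For these 2 lists, leaving out single genes was not tried, so 1 locus with many regions could carry the value. The natural killer call was lost with quantile normalization (adjusted permutation p = 0.0595) and with the added centring (0.115), the range over 4 alternatives being 0.0021 to 0.115. Olfactory receptor genes gave 0.03 (345 regions near 264 genes, adjusted permutation p = 0.0021), and no other list passed within 50 kb. Random lists were matched on the number of genes and not of regions. Olfactory receptor genes have few regions each, so random lists of as many genes rest on more regions, and this p may be too small. Random lists had medians near -0.03. Within 20 kb, macrophage regions also passed as higher in replicate 2 (0.13, adjusted permutation p = 0.00105). So did T cell (0.08), endothelial (0.09) and stroma regions (0.08), each with adjusted permutation p = 0.0336. Macrophage regions also passed among shared regions above the median signal (0.14, adjusted permutation p = 0.00672). None of these added lists passed with quantile normalization or centring within bins. With 1 library per biological replicate, these values describe 2 samples and test no condition.

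**Figure D3:**
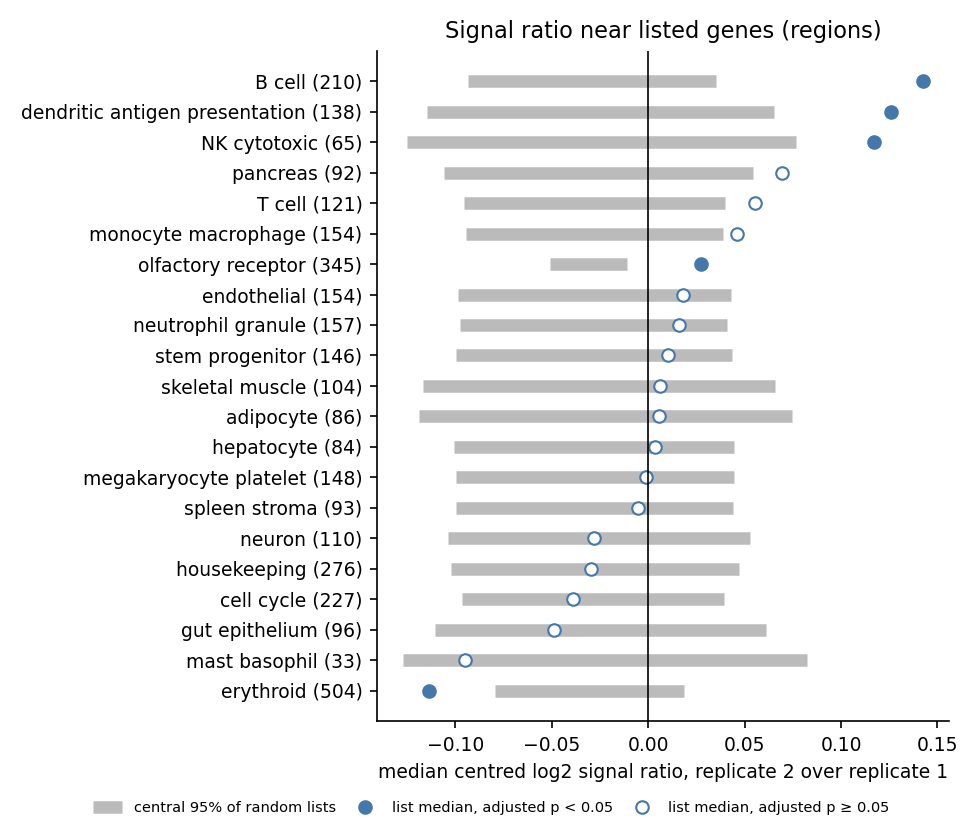
Points give each list's median log2 ratio of signal, replicate 2 over replicate 1, at shared regions within 50 kb of its genes, centred on all shared regions, with the number of regions in brackets and filled points for adjusted p under 0.05. Grey bars span the central 95% of 10000 random lists; erythroid regions lie at -0.11 and B cell regions at 0.14, outside their bars.

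Promoters held 34.4% of the shared regions, against 2.23% of shuffled regions. A further 4.26% lay in exons, 30.4% in introns and 30.9% between genes, counting protein-coding genes only. Promoters held 19.1% of the regions found in replicate 1 only and 13.1% of those found in replicate 2 only. By library, 31.2% of the regions of replicate 1 and 28.1% of those of replicate 2 lay at promoters, a mean of 29.6% ± 2.22 (n = 2). Promoter regions were stronger than distal ones, those over 1 kb from any start site, with a median signal of 2.39 ± 0.323 against 0.831 ± 0.0418 (n = 2). They held 3.63 ± 0.0747 footprints per region against 2.65 ± 0.184. The share of shared regions with at least 1 footprint was lower at promoters in both libraries, 88.3% against 92.2% in replicate 1 and 90.1% against 94.5% in replicate 2. With each library's own regions this difference was smaller in replicate 1, at -0.760 percentage points, and turned in replicate 2, at 2.46. Within quintiles of signal in replicate 1 it ranged from -26.2 points in the middle quintile (70.2% against 96.4%) to -0.00886 in the strongest. No test between samples was made.

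Footprints were shared less often than peaks. Of the footprints of replicate 1, 62.1% overlapped one of replicate 2, and 52.2% of those of replicate 2 overlapped one of replicate 1 (mean 57.2% ± 7.01, n = 2). Within shared regions the shares were 68.1% and 62.2%, against 34.2% and 32.0% for footprints shuffled within the same regions. Footprints had a median width of 11 bp in replicate 1 and 10 bp in replicate 2.

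Footprints were rich in matches to the site of CTCF, which organises chromatin loops, and to several other sites. Of 81498 footprint windows in shared regions, 2611 held the CTCF consensus CCASYAGRKGGC, against 7 of as many control windows in the same regions (odds ratio 360, 95% interval 176 to 737). The ratio rests on few control matches and was 143 in replicate 1 alone, 216 in replicate 2 alone and 858 without flanks. Among motifs with at least 50 matches, the next largest odds ratios were those of REST, a repressor of neuronal genes (CAGCACCNNGGACAG, 95 against 0, odds ratio 191, 95% interval 11.9 to 3079), the GC box of SP factors (GGGGCGGGG, 2834 against 164, 17.8), NRF1 (GCGCANGCGC, 1037 against 62, 16.8) and CREB (TGACGTCA, 339 against 24, 13.9). The full NF1 site had fewer matches (TTGGCNNNNNGCCAA, 40 against 0, 81.0). Where the control count is 0, the ratio is set by the 0.5 added to each cell. In replicates 1 and 2 alone the ratios were 32.7 and 42.6 for REST, 8.88 and 11.6 for the GC box, 9.38 and 15.0 for NRF1, 8.68 and 9.44 for CREB and 97.0 and 35.0 for NF1, so the order of the GC box and NRF1 turned. The CCAAT site of NFY did not pass (769 against 783, odds ratio 0.982), and in replicate 1 alone it was less frequent in footprints (0.849, adjusted p = 4.18e-04, Fisher's exact test). With the same limit, the smallest were those of FOXA (TGTTTACW, 28 against 130, 0.218), NKX2 (CCACTTAA, 15 against 46, 0.333), the PU.1 and IRF composite (GGAANNGAAA, 79 against 163, 0.486), HNF4 (CAAAGTYCA, 21 against 40, 0.531) and TEAD (RCATTCCW, 134 against 207, 0.648). Among sites of blood factors, named after their values were seen, the CACCC site bound by KLF1 was in 10.3% of footprint windows and 1.54% of control windows (odds ratio 7.34). Every GC box match also holds the CACCC consensus used here. The 2834 footprint and 164 control windows with a GC box are therefore among those counted, and the value is not particular to KLF1. The odds ratio was 6.83 for NFE2, 4.42 for EBF and 2.38 for the composite of GATA and TAL1 sites. It was 0.845 for the single GATA site and 0.650 for PU.1. By Fisher's exact test with Benjamini-Hochberg adjustment over 38 motifs, 18 were more frequent in footprints, 12 were less frequent and the others did not pass.

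Base composition bears on these counts, since footprint windows had 62.7% G and C and control windows 56.6%. The same consensus read in reverse, which keeps composition, gave 5.29 for the CACCC site, 6.15 for NRF1, 2.39 for EBF, 0.302 for the GATA and TAL1 composite, 0.630 for GATA and 0.415 for PU.1. The GC box reads the same in reverse, so this control says nothing about it. Every GC box match also holds the reversed CACCC consensus, so the value of 5.29 does not reflect composition alone. In the libraries alone the odds ratio was 0.549 and 0.626 for NKX2, and it was 2.68 for EBF in replicate 1 and 4.24 in replicate 2. The HNF4 call was lost in each library alone (odds ratios 0.844 and 1.35), and the single GATA call in replicate 1 alone (0.960). The call for the NF-kappaB consensus (odds ratio 1.25) was also lost in replicate 1 alone (1.09). The reversed consensus gave a larger odds ratio than the consensus itself for NF-kappaB (2.27) and for E2F (2.83 against 2.29), so this control does not set these 2 calls apart from composition. Nor does it for several sites that were less frequent in footprints, whose reversed consensus was lower still. These include HNF4 (0.343 against 0.531), TEAD (0.409 against 0.648), STAT (0.285 against 0.747), the POU octamer (0.360 against 0.690), SOX (0.538 against 0.701) and ISRE (0.645 against 0.719), besides GATA and PU.1. Windows are not independent replicates.

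**Figure D4:**
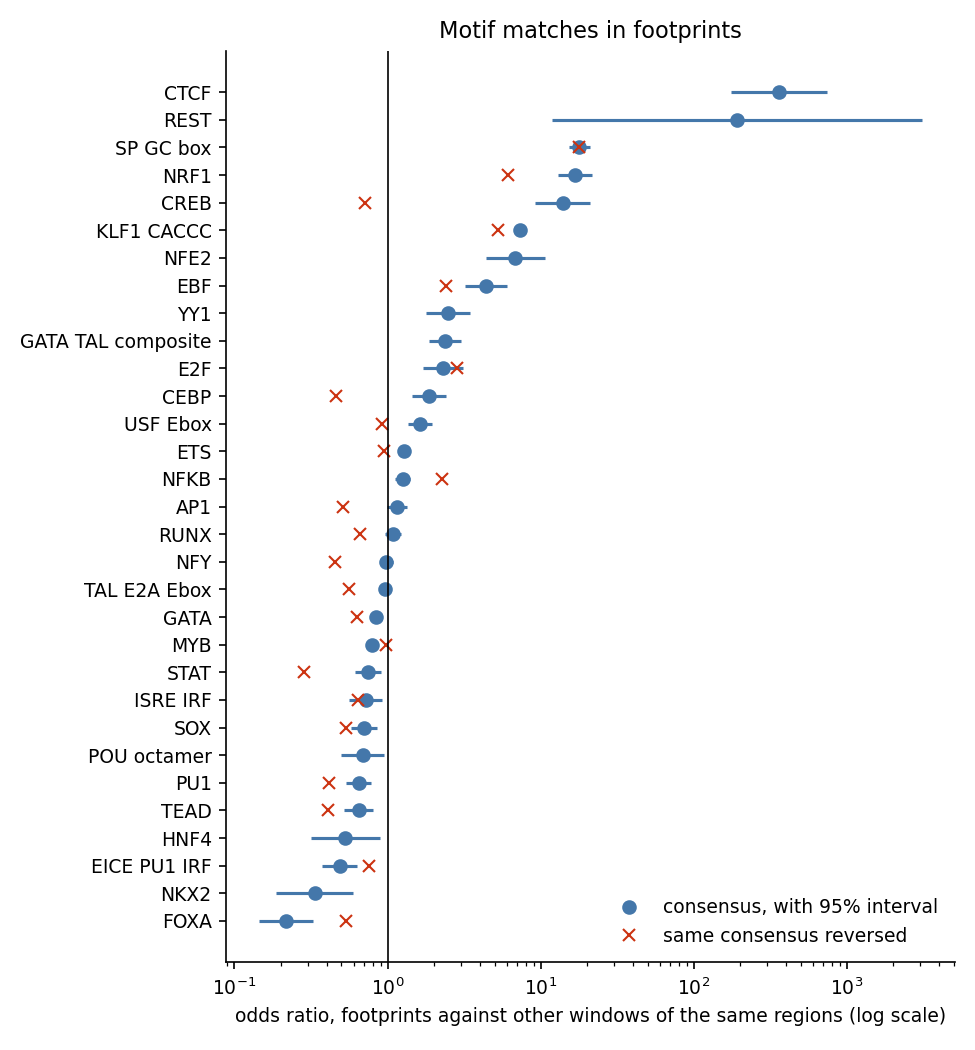
Points give the odds ratio of a consensus match in footprints against other windows of the same regions, on a log axis, with 95% intervals, for motifs with at least 50 matches, and crosses give the same consensus reversed. CTCF (360) and REST (191) stand highest and FOXA (0.218) lowest.

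The X chromosome had fewer and weaker regions than every autosome. It held 9.25 shared regions per Mb, against a median of 23.8 over the 19 autosomes (17.2 to 40.4), a ratio of 0.388. Per protein-coding gene the ratio was 0.558. The median signal on X was 0.626 times the autosomal median in both replicates. Males carry a single X chromosome. No test between samples was made.

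The strongest shared region outside promoters lay between genes on chromosome X, 143482981 to 143483140, 35530 bp from the start site of Pak3, with a signal of 134 in replicate 1 and 72.4 in replicate 2. The others among the first 5 lay on chromosome 17 from 39846781 to 39846900, between genes and nearest to Esp38 (40.4 and 54.3), on chromosome 15 from 99735661 to 99736040, in an exon with the nearest start site at Cox14 (41.9 and 44.6), on chromosome 9 from 3002041 to 3002240, in an intron with the nearest start site at Gm11168 (39.1 and 45.5), and on chromosome 9 from 123461921 to 123462080, in an exon with the nearest start site at Limd1 (36.4 and 36.8). In those near Esp38, Gm11168 and Limd1, most 31-base words occur more than once in the reference. Only protein-coding genes were annotated, so a region called between genes may lie in a non-coding gene, such as one of ribosomal RNA. Among regions above the median signal, the largest excess in replicate 2 was between genes on chromosome 18, 45845261 to 45845406, nearest to Kcnn2 (0.333 and 2.76). It was followed by regions nearest to Pdia4 (chromosome 6), Dusp6 (chromosome 10), Btnl2 (chromosome 17) and Slc10a2 (chromosome 8). The largest excess in replicate 1 lay at the promoter of Gm10717 on chromosome 9, 3031021 to 3031200 (4.47 and 0.846), with another beside it at 3026861. The next was in an intron of Ank1, the red cell ankyrin gene, on chromosome 8, 23095561 to 23095740 (7.57 and 1.52). Regions nearest to Fbln1 on chromosome 15 and Zfp958 on chromosome 8 followed. Several of these regions lie in repeats masked in the reference, with 94.5% of bases masked near Kcnn2, 100% near Dusp6 and Slc10a2, 91.1% and 100% at the 2 regions of Gm10717, 69.4% in Ank1, 46.9% near Fbln1 and 18.6% near Zfp958. None were masked near Pdia4 and Btnl2.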

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

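The counts in this part were chosen after the data had been seen, no explanation of them was tested, and they concern signal outside the peaks that the comparisons rest on.

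Some stretches with an FDR of at most 0.001 lay outside the peaks of both libraries, 9827 in replicate 1 and 12775 in replicate 2. Of these, 491 of replicate 1 and 508 of replicate 2 overlapped a stretch of the other library outside that library's own peaks. The overlap expected by chance was not computed. Stretches of the other library that touch its peaks were not compared, so the rest need not be particular to 1 library. Most of the 491 and 508 lay beside known peaks, 481 and 501 of them within 500 bp of one, and 10 and 7 lay farther away. Stretches at this FDR outside the peaks of their own library had a median length of 3 bp in both libraries. Those touching a peak had medians of 188 and 167 bp. The stretches outside held 0.74% and 0.89% of all bases at this FDR.

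Footprints outside the peaks of their own library numbered 30853 in replicate 1 (14.2%) and 39509 in replicate 2 (15.6%).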

How the results depend on the processing

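Means in place of medians and the centring within bins were chosen after seeing the data; all other alternatives were planned. Where a value moved, the cause was not tested.

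The mean peak overlap of 73.5% became 79.7% with the stricter list, 65.2% with reciprocal overlap and 89.1% with the stronger peaks, and the correlation of log2 signals stayed at 0.978 with reciprocal overlap. The promoter share of 34.4% ranged from 28.1% to 31.2% in the libraries alone and was 42.0% with the stricter list, 27.2% within 500 bp and 41.5% within 2500 bp. The mean overlap of footprints fell to 43.1% with reciprocal overlap. A stricter footprint threshold could not be run, since every footprint carries the same FDR.

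Lists with fewer open promoters numbered 9, but 14 with the stricter list, 14 with the stronger peaks and 1 among CpG-poor promoters, where the odds ratio became 1.09 for natural killer, 3.90 for neutrophil and 1.44 for muscle genes. Lists with more open promoters numbered 3 to 5. Erythroid, cell cycle and housekeeping genes passed in each alternative that gave a test, cell cycle and housekeeping lists having no CpG-poor test. Lists with more regions within 50 kb numbered 2, 3 within 20 kb, where cell cycle genes joined, and 4 by the mean. Lists with relatively more signal in replicate 2 numbered 4, and 8 within 20 kb, where the stroma median turned to 0.0835. Lists with less numbered 1, and 2 with centring within bins, where mast cell genes joined. Erythroid and B cell genes kept their direction and call in all 4 alternatives.

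The promoter minus distal share of regions with a footprint was -4.18 percentage points, -0.760 to 2.46 in the libraries alone, -6.71 with the stricter list and -11.3 within quintiles of signal. Motifs more frequent in footprints numbered 18, and 6 with the reversed consensus, which turned the odds ratio to 0.302 for the GATA and TAL1 composite, 0.949 for ETS, 0.658 for RUNX, 0.917 for USF, 0.511 for AP1, 0.20 for NFE2, 0.709 for CREB and 0.464 for CEBP. In the libraries alone the odds ratio was 1.02 to 1.06 for the TAL1 and E2A site (0.967 with both), 0.849 to 1.06 for AP1 (1.15 with both) and 0.844 to 1.35 for HNF4. The X to autosome ratio of regions per Mb, 0.388, was 0.405 to 0.434 in the libraries alone and 0.558 per gene. Depth is unknown, and it limits which weak peaks one library could share with the other. No paired analysis was possible because there is 1 group.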

Other observations

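The gene families, the word count of the region near Cox14, the centring within bins and the values by consensus in the last paragraph were chosen after the patterns had been seen, as were the patterns themselves; apart from that word count, what each test would show was written before its result.

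Gene families defined by symbol, some with members in the fixed lists, were also counted, taking as open the genes with a promoter peak in each library. Ribosomal protein genes were open in 75 of 76 cases, with a median promoter signal of 10.1 ± 0.550 (n = 2), proteasome subunit genes in 37 of 39 (10.3 ± 2.0) and replication-dependent histone genes in 60 of 67 (5.74 ± 0.101). All 9 interferon regulatory factor genes were open (3.26 ± 0.268), as were all 3 RUNX genes (1.74 ± 0.0693) and 15 of 17 KLF genes (7.88 ± 0.395). Zinc finger genes named Zfp were open in 309 of 365 cases and genes with symbols beginning with Itga, Itgb or Itgl in 22 of 31. The latter hold the integrin genes and can include genes that do not encode integrins. Toll-like receptor genes were open in 8 of 12 cases and chemokine receptor genes in 6 of 16, namely Cxcr2, Cxcr3, Cxcr4, Cxcr5, Ccr7 and Ccr9. Of the GATA factor genes, Gata1, Gata2 and Gata6 were open.

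Of the Hox genes, which set position along the body axis, the Hoxa cluster had 5 of 11 open promoters, among them Hoxa5, Hoxa7 and Hoxa10. Hoxb had 2 of 10, at Hoxb4 and Hoxb5, Hoxc had 1 of 9, at Hoxc10, and none of the 9 Hoxd genes was open. Keratin genes were open in 3 of 53 cases, beta defensin genes in 2 of 42 and vomeronasal receptor genes in 1 of 326, which was Vmn1r4. These counts were not tested.

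The signal near erythroid genes was relatively lower, and that near B cell genes higher, in replicate 2. A trend with signal, GC content or promoter class was argued against as the whole cause, since centring the ratio within bins of all of these left medians of -0.11 and 0.15 (adjusted permutation p = 0.0021 for both, ranges over alternatives 0.0021 to 0.0231 and 0.00105 to 0.0021). Single genes with many regions were argued against as well, since the median nearest to random lists was -0.11 without Alas2 and 0.12 without Pax5, outside their 95% ranges, and 36 of 46 erythroid and 23 of 26 B cell genes lay on the list's side. Another mixture of the cell lineages in the 2 samples is a candidate explanation. In distal regions over 50 kb from every listed gene, regions with an EBF site were set against those with a GATA and TAL1 composite. Regions with both were left out, and the log2 ratio centred within bins was used. The medians were 0.12 at 410 EBF regions and -0.23 at 1235 composite regions. Their difference was 0.34 (permutation p = 1e-05, the smallest that 100000 permutations can give), and 0.35 without the centring within bins. Regions were the units of this permutation and are not independent replicates, so its p concerns regions of these 2 libraries and no difference between animals. Whether such a difference came from the animals, from dissection or from blood left in the tissue was not tested, and the design has no groups from which a biological explanation could be tested.

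Some of the strongest distal regions may reflect sequence present in several copies. Of the 50 strongest, 22% had over 50% of their 31-base words repeated in the reference chromosomes, against 2.8% of 500 other distal regions (odds ratio 9.77, p = 2.0e-06, Fisher's exact test). The region near Gm11168 had a median of 37 copies per word, whereas 0% of the words of the region near Cox14 were repeated, which argues against repeated reference sequence there. Copies missing from the reference and the placement of reads with several matches could not be tested. No word matched the mitochondrial genome in the 5 strongest regions, and no biological explanation was tested.

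The missing promoter peaks at 3 erythroid genes may likewise come from reads shared between near-identical copies. Repeated words made up 75.0% of the 1 kb either side of the start site at Hba-a1, 81.0% at Hba-a2 and 100% at Slc25a37, and none of the 43 open erythroid promoters exceeded 50%, their median being 1.01% and their highest, at Hbb-bs, 44.4%. Repeated sequence thus went with missing peaks here and with strong peaks at distal regions, and how reads with several matches were handled is not given in the sources used here. A first count that included alternate strain loci was replaced by one over the chromosomes and the mitochondrial genome. No biological explanation was tested.

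Regions with other consensus matches also differed between the replicates, as values without a test. After the same centring within bins, the median log2 ratio of replicate 2 to replicate 1 at distal regions away from every listed gene was -0.17 with the NFE2 consensus, -0.13 with GATA and -0.06 with the CACCC site of KLF1. It was 0.07 with the octamer of POU factors, 0.06 with the PU.1 and IRF composite, 0.06 with PU.1 and 0.04 with CTCF. Other consensuses gave values of similar size, 0.07 with E2F, 0.05 with NKX2 and 0.04 with HNF4, and the CEBP site of myeloid factors gave -0.05. The AP1 consensus, which every NFE2 match contains, gave -0.06. The GC box, whose matches all hold the CACCC consensus, gave -0.04. The smaller values therefore do not separate lineages.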
